A study of Schizosaccharomyces pombe with 22 samples.

How the data were processed

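The text rests on the processed tables of the series and its sample labels. Per the labels, 12 lariat libraries came from the dbr1 deletion, made from total RNA with a custom protocol that keeps no strand, as long and short gel fractions of 2 replicates in 3 conditions. Per the labels, 10 polyadenylated RNA-seq libraries came from wild type and the dbr1 deletion (1 library per strain and condition) and from strain ED668 and its upf1 deletion (2 libraries each), and cells grew at 30 °C outside heat shock.

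Lariat counts were used as deposited, as whole read counts per 5' splice site and branch point, summed by the authors over the libraries of a condition and not scaled for depth. RNA-seq junction counts were used as deposited, as whole counts per junction and library, with aligned reads per library given by the authors. The fraction values headed PSI were made by the authors before the files were deposited, with a denominator that is not given in the sources used here. The other values, namely positions, lengths, read classes and conservation estimates, were assigned by the authors against their own annotation, as deposited. The aligner is not given in the sources used here. The build was ASM294v2 per the submitters' processing notes, and positions were checked on the ASM294v3 reference: all 17799 branches (8391 forward, 9408 reverse) began with GT and had an A as branch point. Of 4701 annotated introns 4629 were found by gene and intron number in the reference annotation, 4518 of them with a listed length 1 base above the reference length. Gene names came from the name table for 4699 introns. The strand of junctions came from their splice sites.

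The sheets gave 1 lariat column per condition, so the planned tests between lariat libraries could not be run and lariat values are ratios with exact 95% counting intervals. Ratios were scaled by the annotated branch reads of each condition, and fold values with 1 to 3 reads on a side are given with their interval. For 0 reads the bound sets 3 reads in place of 0. Values given as at least in this way leave out counting error and are not 95% limits, which can lie nearer to no change. Ratios were also taken minus the running median over 101 introns ordered by length, with a pseudocount of 0.5, and lists were set against 10000 random lists of the same size drawn from genes with like read numbers, a gene taking the median of its introns. The depth-scaled list values used reads summed per gene, with random lists matched on reads and on intron length. Introns needed 50 reads in the higher condition. Shares use Wilson intervals, and alternate rates use host introns with at least 100 reads. The rate or share of a single alternate is its reads over its own plus the annotated host reads, so other alternates of that intron are left out. Exon skip ratios were also resampled over events 10000 times. Exon skip lariats were expected from length with 14 bases added after the branch point.

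RNA-seq junctions were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3, TMM scaling, filterByExpr with a minimum count of 10), with strain as covariate for growth conditions and condition as covariate for dbr1. Values are called at Benjamini-Hochberg adjusted p below 0.05. Alternates and unannotated junctions were joined for the growth and dbr1 tests (27 and 70 junctions). They were tested apart for upf1, because the deletion columns of the unannotated table carry no number, and there the mean of the 2 aligned totals served as library size. DESeq2 1.42.0 was the second tool. The planned comparison of each junction with its annotated intron in RNA-seq is not analysed here, nor are gene-level values, so dbr1 and upf1 themselves are not reported. Other software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and pysam 0.24.0. In simulated counts with log2 changes of 2 and a dispersion of 0.02, between 86.4% and 100% of changed junctions were recovered, and counting intervals covered the true ratio in 96.4% of 2000 draws.

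Before the data were examined, the tests, the naming rule and all alternatives but those named below were fixed. The rule took the 10 features with the largest log2 change in each direction among those that passed and moved alike in every replicate or strain. For lariats it took the 10 largest ratios in each direction, and for events the 10 with the most reads and the 10 with the highest rate. From each list up to 4 members with the largest change were taken. The lists were heat shock proteins, core stress response, glucose-repressed and respiration genes, glycolysis, cytoplasmic ribosomal proteins, ribosome biogenesis, splicing factors, RNA decay, and meiosis and mating. The ribosomal protein list took every gene named rpl, rps or rpp with a number. It therefore held rpp1 and rpp40 by name alone, and they need not encode ribosomal proteins. Added after the values were seen were the ranking against introns of like length with the introns named from it, random lists matched on length, either assignment of the aligned totals or of the replicate block to the unnumbered deletion columns, rates without branch points near the annotated 3' site, ratios without the 10 largest skips, and ratios with the incomplete branches included. Permutation tests used 100000 draws.

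Branches whose condition counts fell short of their total were left out of condition ratios, and branches in no class list were left out of class counts. The per-sample tables held 2 columns that were not used. The alternatives were other scalings, filters, read minimums and thresholds, leaving out single libraries, and the replicate number as a block.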

Results

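Introns of Schizosaccharomyces pombe were read in 2 ways, as the lariat loops that splicing leaves behind and as exon-exon junctions of polyadenylated RNA. Lariat sequencing was done on cells lacking dbr1, the enzyme that opens lariats, in rich media, after heat shock and after the diauxic shift, when glucose runs out and cells turn to respiration. The branch reads place a 5' splice site and a branch point on the genome. RNA-seq was done on wild type and the dbr1 deletion in the same 3 conditions, and on strain ED668 with and without upf1, the helicase of nonsense-mediated decay.

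The 12 lariat libraries were deposited as 1 sum per condition, with 53284863 reads in rich media, 9467948 in heat shock and 9854589 in diauxic shift. Lariat comparisons therefore have no replicates, and their 95% intervals cover counting error only, since reads were not told apart from PCR copies. The 10 RNA-seq libraries held 12330328 to 36500561 aligned reads. Of 3790260 branch reads, 3446224 lay at annotated introns, 99154 at alternate sites of annotated introns, 202844 at unannotated introns and 2084 at exon skips. Transcript levels of dbr1, upf1 and other whole genes are not analysed here.

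The introns with the most lariat reads included several of ribosomal protein genes. The rps13 intron, in a gene of the small ribosomal subunit, led with 203284 reads, followed by rps2402 with 122565 and rpl31 with 85313. After these came put2 with 73305, the asparagine synthetase gene asn1 with 60268, rps1201 with 44495, the calcium sensor gene ncs1 with 37347, the kinase gene sck1 with 37158, met14 of sulfate assimilation with 33342 and pdc2 with 33092. Reads were found for 2812 of 4701 annotated introns (59.8%, 58.4 to 61.2). Recovery depended on length: 17.8% of introns under 51 bases had reads, 71.6% of those of 51 to 75 bases and 98.1% of those of 76 to 100 bases. More than 1 branch point was seen in 829 introns, but 98.86% of annotated reads lay at the most used branch point of each intron.

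**Figure D1:**
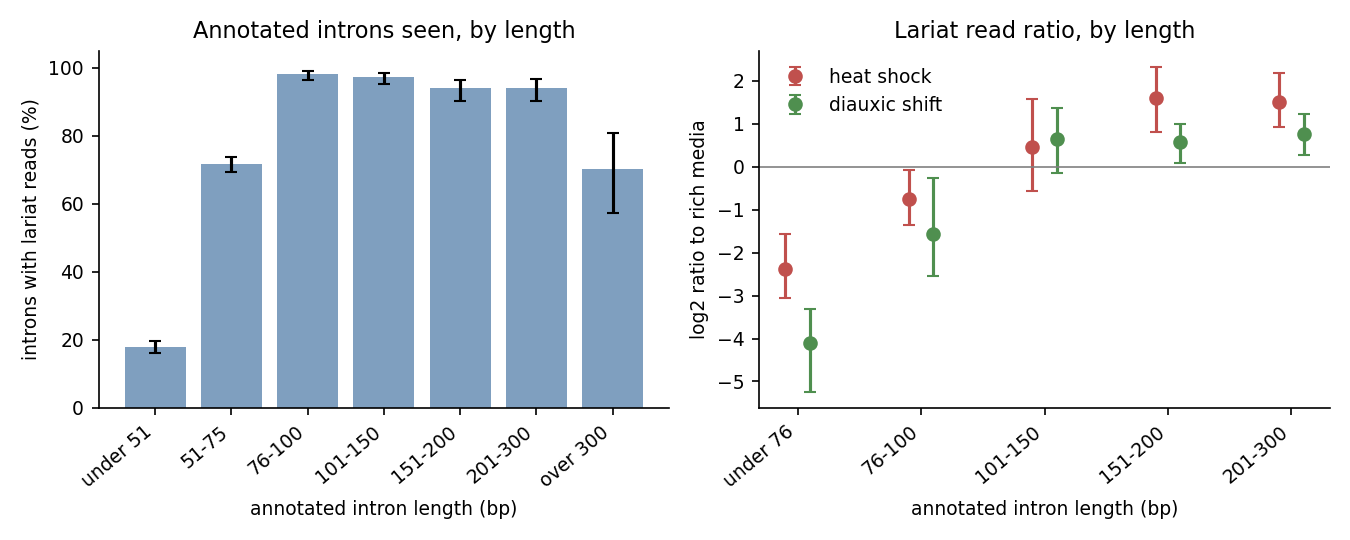
Recovery of annotated introns by length, and condition ratios of lariat reads by length. Introns under 51 bases were recovered in 17.8% of cases, and the median log2 ratio of heat shock to rich media ran from -2.38 under 76 bases to 1.60 in the class that ends at 200 bases.

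After heat shock, the highest lariat ratios to rich media lay in genes of varied function. The largest was at intron 1 of res2 (chromosome I, 686825 to 686988), which encodes a subunit of the transcription factor of the G1 to S transition. Its lariats went from 2 reads to 86, a ratio of 130.0 (34.9 to 1090.5). Intron 2 of spp27, a factor of RNA polymerase I, came next at 61.1-fold (32.5 to 129), then the ribosomal protein introns of rpp101 at 22.5-fold (15.7 to 32.9) and rpl3601 at 18.9-fold (13.02 to 28.1). The other introns in the highest 10 were those of gcs2 at 15.0-fold, fps1 at 14.1, the frataxin gene fxn1 at 13.5, osh41 at 13.1, the prolyl isomerase gene fkh1 at 12.6 and SPAC2F3.18c at 12.5. At the other end stood introns with reads in rich media and none in heat shock, where 3 reads set a bound that leaves out counting error. The mitochondrial ribosomal gene mrpl33 had 161 rich reads and was at least 17.8-fold lower, mis16 of the centromere at least 10.9-fold, tif211 of translation initiation factor eIF2 at least 10.3-fold and the proteasome ATPase gene rpt1 at least 10.03-fold. The bound was at least 10.2-fold for naa20, 7.83-fold for caf16, 7.06-fold for rdl2, 6.84-fold for the clathrin gene chc1, 6.62-fold for cdc27 of DNA polymerase delta and 6.40-fold for dtd1. These values use a heat scale of 0.331 relative to rich media, and with the 0.178 of read totals every ratio would be higher and every bound smaller by the same factor.

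Part of these ratios followed intron length, with higher ratios at long introns (Spearman rho 0.815 between length and ratio). Whether this came from recovery or from the RNA itself was not tested. Ratios were therefore also taken against introns of like length, which removes the dependence (rho 0.00123) and does not hang on the scaling of the libraries. With this view 177 introns stood more than 2-fold above their length peers and 206 below, out of 1299. The log2 interval of res2 (5.12 to 10.09) lay above the 1.87 expected at its length, by 4.84 at the fitted value from 2 rich reads. Intron 2 of spp27 stood 4.24 log2 units above its peers, rpp101 2.78 and rpl3601 2.28. New at the top were SPBP8B7.32 at 3.12, guf1 of mitochondrial translation at 3.10 and the ubiquitin-conjugating enzyme gene ubc4 at 2.98 (1552 rich reads and 1894 heat reads). Below their peers stood the SNARE gene tlg1 at -3.62 (352 and 6 reads) and the mitotic kinesin gene klp9 at -3.27 (285 and 27 reads). The tif211 intron, with 0 reads after heat, was at least 8.90-fold below its peers, against at least 3.47-fold for mis16 and 2.29-fold for mrpl33.

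Where the fixed lists stood in heat shock depended on the measure. The ratio to length peers took the median of a gene's introns and the depth-scaled ratio summed its reads, so more than the length step differs. For meiosis they also covered 8 and 10 genes. Of 13 RNA decay genes 8 were below their length peers and 4 above, with a median log2 of -0.65 at percentile 1.3 of random lists. By the depth-scaled ratio with random lists matched on length, the percentile was 21.02. They included dis3 of the exosome at -2.33, rmn1 at -1.74 and the decapping enhancer gene edc3 at -1.66, while not2 of the deadenylase complex went the other way at 1.86. Ribosomal protein genes were spread around their peers (29 higher and 23 lower of 52, median 0.13, percentile 71.1, and 93.1 with matched lists), from rpp101 at 2.78 to rpl14 at -2.63. Splicing factor genes leaned lower without standing apart (8 higher, 15 lower of 24, median -0.22, percentile 22.3, and 19.2 with matched lists), although snu13 of the U4/U6.U5 particle and cwf12 each stood at 1.49. Genes of respiration (13, median 0.03, percentile 52.4, and 78.2 with matched lists, from atp15 at 2.34 to cox12 at -1.59) and of meiosis (8, median 0.29, percentile 85.4, and 45.8 with matched lists, from mcp7 at 1.41 to map1 at -1.38) lay among the random lists. Ribosome biogenesis had a median of 0.13 over 7 genes (percentile 63.9, and 5.55 with matched lists), from utp20 at 0.78 to dbp2 at -0.85. Few introns of stress genes passed the read limit. The thioredoxin reductase gene trr1 was 4.08-fold higher (2.66 to 6.30), trx2 lay at 0.387, and the Hsp90 co-chaperone gene wos2 at 0.872 (0.714 to 1.06). No glycolysis intron passed it. By the depth-scaled ratio alone, 286 introns were more than 2-fold higher and 544 lower of 1299. The split of higher and lower introns was 487 and 812 with that scaling and 718 and 581 with read totals, as the median moved from -0.66 to 0.24.

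After the diauxic shift, 37 of 49 ribosomal protein genes lay below introns of like length and 12 above, and those with many reads went either way. Their median was -0.41 at percentile 0.33, and no percentile here is corrected over the lists. This place was not kept by the depth-scaled ratio with random lists matched on length, at percentile 13.5 (20 higher and 29 lower). Of the introns with the most reads in this group, rps13 (41708 and 137953 reads) and rpl31 (18416 and 62230) stood higher in diauxic shift and rps1201 (37307 and 2740) lower. The lowest were rpl2301 at -3.05, rps2501 at -2.26, rpl3802 at -2.04 and rpl14 at -1.83. Ribosome biogenesis had 5 of 7 lower and a median of -0.77 at percentile 3.02, and 4.98 with matched lists, drawn from the helicase gene dbp2 at -1.73 and the snoRNP genes nop58 at -0.82 and gar1 at -0.77. Meiosis genes had 7 of 8 above their length peers and a median of 0.79 at percentile 98.3, but 2 higher and 8 lower of 10, a median of -0.55 and percentile 77.7 by the depth-scaled ratio with matched lists. Against peers the autophagy kinase gene atg1 (80 and 24 reads) stood at 2.25, map1 at 1.82, mcp7 at 0.97 and the cohesin gene rec11 at 0.93. Without the length correction the ribosomal protein median was -0.60 and turned to 0.26 under TMM scaling, and the meiosis median turned to 0.32.

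Single introns reached larger ratios. SPAPB1A11.02 went from 2 to 114 reads, a ratio of 56.1 (15.2 to 469), and vps68 of the vacuolar sorting pathway from 7 to 259 reads, or 36.4-fold (17.4 to 91.5). They lie on chromosome I (2980533 to 2980629) and chromosome II (1362339 to 1362460). Next were yip11 at 17.2-fold, SPBC2A9.14 at 15.5, the mitochondrial superoxide dismutase gene sod2 at 14.8 (5.48 to 55.9), the recombination gene rti1 at 14.3 and nbs1 of the Mre11 complex at 10.6. Then came meu26 at 10.5 and mug182 at 10.04, both named for raised expression in meiosis, and the nuclear import gene kap104 at 9.79. The log2 interval of SPAPB1A11.02 (3.92 to 8.87) lay above the -0.07 expected at its length. Against length peers vps68 stood 4.01 log2 units higher, mug95 4.34, the meiotic poly(A)-binding gene crp79 3.71, rsm7 of the mitochondrial ribosome 3.10, the Rab GTPase gene ypt5 3.05 and the polyadenylation factor gene yth1 3.05.

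Introns with rich reads and 0 diauxic reads included ste13, the decay helicase, with 210 rich reads and at least 71.1-fold, the cyclophilin gene cyp3 at least 70.1-fold, rps29 at least 67.1-fold and the proteasome gene pre5 at least 52.5-fold. The exocyst gene sec8 was at least 48.1-fold lower, the phenylalanyl-tRNA synthetase gene frs1 46.4, sap61 of the U2 snRNP 41.7 and the ubiquitin ligase gene pub1 40.3. The replication nuclease gene dna2 had 2749 rich reads and 9 diauxic reads (ratio 0.00322, 0.00147 to 0.00613), and rsc4 of the RSC remodeller 425 and 1 (ratio 0.0023, 5.85e-05 to 0.0130). Short introns dominate this end, and ste13 and sap61 could not be placed below their length peers by the 3-read bound. Clear of that limit were thg1, which edits the histidine tRNA, at -3.58 against its peers (657 and 48 reads), and the ribosome assembly gene rpf2 at -3.36 (384 and 62 reads). The chromatin gene arp6 of the SWR1 complex, with 0 reads, was at least 2.51-fold below its peers.

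RNA decay genes in diauxic shift had a median of -0.34 over 13 genes (percentile 12.6, and 61.2 with matched lists), or -0.17 with unseen introns set at 3 reads, with rmn1 at -2.02 and dis3 at -0.93. Respiration had 0.20 over 13 genes (percentile 69.2, and 95.7 with matched lists), with atp15 at 2.18, cyt1 at 1.51, cox13 at 1.38 and qcr9 at -1.23. Splicing had 0.21 over 25 genes (percentile 79.6, and 24.2 with matched lists), with lsm6 at -2.11 and prp4 at -1.76. Of the core stress list only sod2 at 14.8-fold and trx2 at 0.935 were measured, of the heat shock list only wos2 at 0.852, and of glycolysis none. Depth-scaled diauxic ratios used a scale of 1.016 relative to rich media, against 0.560 by TMM and 0.185 by read totals. With those scales every ratio would be higher and every bound on a fall smaller by the same factor, and trx2 and wos2 would turn above 1. Ratios again followed length (rho 0.823, and -0.0151 after correction). More than 2-fold from their peers were 207 introns above and 227 below of 1338, against 227 and 649 by the depth-scaled ratio. That scaling put 502 introns higher and 836 lower, TMM 671 and 667 and read totals 878 and 460, with medians of -0.84, 0.02 and 1.62.

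Exon skips held few lariat reads. Lariats joined the 5' site of an intron to the branch point of a later one at 230 skips in 190 genes, and 219 of them left out a single exon. The skips with most reads were in mgs1 (88 reads), pth1 (81), SPCC663.18 (79), SPCC126.11c (72), pwi1 (72), the replication checkpoint kinase gene cds1 (70), SPAC1002.07c (68), the tRNA deaminase gene tad1 (56), atg44 (49) of mitochondrial division and bqt4 (47), which ties telomeres to the nuclear envelope. With the host introns, the skip made up 15.9% (12.8 to 19.6) of lariat reads in cds1, 91.1% (82.8 to 95.6) in pwi1, 97.3% (90.7 to 99.3) in SPCC126.11c and 98.6% (92.2 to 99.7) in SPAC1002.07c. No host read was seen in mgs1 (95.8 to 100%), pth1, SPCC663.18, tad1, atg44 and bqt4 (92.4 to 100%). Short introns seldom gave lariats (17.8% under 51 bases), so missing host reads need not mean that the host introns were left unspliced. With at least 100 host reads only cds1 stood above 2%, followed by the ubiquitin ligase gene pub1 at 1.63% (0.447 to 5.74) and the splicing gene srp2 at 1.27% (0.645 to 2.49). Skipped exons were short, with a median of 62 bases against 139 for all internal exons, and 31.1% (25.3 to 37.5) had a length divisible by 3, against 37.9% (36.1 to 39.7) of 2811 internal exons. A skip lariat spans the exon and the introns beside it, with a median length of 169 bases. Reads per annotated intron averaged 3153 at 76 to 100 bases and 6.67 over 300, so recovery may favour skips of short exons. Per 10000 annotated reads there were 3.65 skip reads in rich media, 11.02 in heat shock and 5.75 in diauxic shift. The heat to rich ratio was 3.02 (2.65 to 3.44, and 2.34 to 3.84 when events are resampled), and the diauxic to rich ratio 1.58 (1.403 to 1.77). Against the reads expected from lariat length these ratios shrank to 1.25 and 1.02.

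Among introns with at least 100 annotated reads, alternate splice sites carried a small share of lariats in most and a large share in a few. Over 1268 host introns with at least 100 reads, alternate sites held 0.670% (0.662 to 0.679) of reads, split into 0.269% for upstream 3' sites, 0.273% for downstream 3' sites, 0.0537% for upstream 5' sites and 0.0772% for downstream 5' sites. Branches with incomplete condition counts add to the pooled total and to downstream 3' sites, as their rates by condition were lower. The total was 0.517% in rich media, 0.570% in heat shock and 0.661% in diauxic shift, and downstream 3' sites held 0.128%, 0.134% and 0.174%. The other kinds were not lower in every condition, and downstream 5' sites were higher in each, at 0.0798%, 0.0916% and 0.0898%. Downstream 3' sites held 0.0469% without branch points nearer to the annotated 3' site than any listed. The hosts with at least 100 reads held 23033 of the 99154 alternate reads, so these rates cover only that part. Of all branch reads with complete condition counts, alternates made up 2.53% in rich media, 2.74% in heat shock and 2.58% in diauxic shift. Of 2545 alternates with a prediction, 80% (78.4 to 81.5) would bring an earlier stop codon. The highest rate was in the SNARE gene vti1 at 80.7% (77.9 to 83.2). Then came the corepressor gene tup12 at 68.7%, lsc1 of the citric acid cycle at 56.2%, the casein kinase gene cki1 at 54.6% and the autophagy gene atg5 at 50.6%. The listed lsc1 alternate is the intron that the reference annotation has at this 3' site. Which 5' site of lsc1 counts as the alternate therefore depends on the annotation. SPBC1711.15c stood at 43.0%, rpp1 at 39.3%, rps1701 at 39.2%, arx1 at 39.0% and sfc9 of transcription factor IIIC at 38.7%. By read number the first were psg2 with 11152, yih1 with 10530, the SNARE gene ufe1 with 8129, the rRNA methyltransferase gene spb1 with 4700, cqd2 with 4179, lsm5 with 3562, SPAC3F10.16C with 2770, rex2 with 2061, the telomere gene tpz1 with 2002 and the myosin light chain gene cdc4 with 1782. All of these but cqd2 had hosts below 100 reads and are not in the rates above.

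Ribosomal protein genes also led the fixed lists, with rpl35 at 37.4% and rpl3002 at 26.9%. The ribosome biogenesis genes gar1 and utp15 had 6.76% and 5.29%, and the splicing genes srp2, lsm7 and cwf29 had 6.70%, 5.61% and 5.19%. For the others the top members were atp1 of the ATP synthase at 3.97%, spo14 of meiosis at 4.34%, trr1 at 4.55%, not2 at 0.372%, rrp46 at 0.327% and wos2 at 0.101%. Shares also differed between conditions, without correction for the lengths of alternate and host lariats, from which alone a share can move. Those compared below are 3' alternates, except in pro2 and ssb2, and their listed 3' sites follow the distance rule described at the end. For them the reads place a branch point and do not show which 3' site was joined. Each share sets 1 alternate against the annotated host reads alone. In diauxic shift it was higher than in rich media for rpl2502 (15.3 and 51.4%), rpl35 (20.8 and 58.1%), SPBC3E7.11c (6.03 and 28.2%), atp1 (1.38 and 7.94%) and rsm24 of the mitochondrial ribosome (1.88 and 11.2%, 8.89 to 13.98). Another upstream 3' site of the same rpl2502 intron stood at 19.2 and 41.8%, so these values are not shares of all lariats of an intron. It was lower for pro2 (51.1 and 18.7%), the spliceosomal gene cwf29 (8.46 and 1.37%), cox13 (1.13 and 0.346%) and the replication protein A gene ssb2, where 3 diauxic reads gave 0.0745% (0.0253 to 0.219) against 5.77%. In heat shock the share of the Ran GTPase gene spi1 was 9.11% against 24.9% in rich media, and that of SPBC19C2.10 was 31.6% against 14.6%. The genes of this paragraph that are on no list were picked from all alternates with at least 50 reads after the values were seen.

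Lariats also came from outside annotated introns, by number of branches most often from the strand opposite a transcript. By reads, exons (47122), noncoding RNAs (36262) and intergenic regions (32939) stood above antisense introns (26257). Of these branches 30.0% lay antisense to a transcript, 19.3% within exons, 16.7% between genes, 11.97% in 3' untranslated regions, 10.6% in 5' untranslated regions and 6.83% in noncoding RNAs. The unannotated intron with most reads lay in an exon of the fatty acid elongase gene elo1 (chromosome I, 251746 to 251862) with 19896 reads. An intergenic intron on chromosome II (1308191 to 1308417) had 13296 reads and was 5.11-fold higher in heat shock (4.91 to 5.32). Next were SPBP35G2.04c with 12423 reads, the small nucleolar RNA gene snoZ with 7974 and 4643, SPNCRNA.1038 with 6264, gmh6 with 5868, SPAC343.20 with 4080, deb1 with 3632 and the strand opposite SPNCRNA.1471 near SPBC3H7.05c with 2833. That last intron was 7.37-fold higher in heat shock and 6.96-fold higher in diauxic shift. In heat shock an intergenic intron at 1170030 to 1170168 on chromosome I was 10.7-fold higher, the 5' region of the corepressor gene ssn6 5.93-fold, gdh2 of glutamate metabolism 5.02-fold, SPNCRNA.1366 4.85-fold and the 3' region of the U4/U6 snRNP gene prp3 4.46-fold. With 0 heat reads the ubp11 intron was at least 7.56-fold lower and the rog1 intron at least 5.78-fold, while the intron antisense to str2 lay at 0.0625 (0.00746 to 0.232) and that of the translation gene sce3 at 0.0736. These ratios are not corrected for length, and the 10 lowest introns were 45 to 90 bases long against 85 to 227 for the 10 highest.

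In diauxic shift the highest and the lowest ratios both included noncoding and antisense introns, again without correction for length (86 to 125 bases for the 10 highest, 45 to 81 for the 10 lowest). SPNCRNA.1472 had 1 rich read and 124 diauxic reads, a ratio of 121 (21.3 to 4806), the 5' region of the polarity scaffold gene scd2 1 and 51 (49.7, 8.52 to 1999), and the strand opposite SPNCRNA.1595 3 and 103 (33.4, 11.1 to 165). SPNCRNA.1651 beside the succinate dehydrogenase gene sdh8 lay at 27.3 (7.20 to 231), and the intron antisense to the kinesin gene tea2 at 20.4. Those antisense to the hexose transporter gene ght5 (62 rich reads) and in SPNCRNA.1358 (64) had 0 diauxic reads, which is at least 21.2-fold and 21.9-fold lower, and the lyr3 intron lay at 0.0582. An intron at 2562324 to 2562373 on chromosome I went from 701 to 4 reads (ratio 0.00556, 0.00151 to 0.0143).

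Splice sites of unannotated introns kept the basic signals at lower frequency. GTAAGT opened 33.7% of annotated and 15.4% of unannotated introns, GTATGT 23.4% and 9.61%, and the branch motif CTRAY was present in 51.7% and 36.3%. TAG closed 72.1% of annotated introns, whereas unannotated introns ended in TAG in 40.8% and AAG in 31.5%. Alternate 5' sites nearly always lacked GTAAGT (3.14% upstream and 0.703% downstream) and had CTRAY at the branch point in 65.3% and 77.8%. Alternates and unannotated introns were longer than annotated introns with lariat reads, with medians of 107, 103 and 75 bases (permutation p 1e-05, the smallest possible, BH 2e-05). Annotated introns without lariat reads had a median of 46 bases. The permutation test cannot tell such recovery by length from a true difference in length. With at least 10 reads they were 14 and 13 bases longer, against 32 and 28 bases for all. Listed 3' sites of alternates and unannotated introns follow a fixed distance rule described at the end, so their endings are not independent sightings.

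Many lariat introns were also seen as junctions of polyadenylated RNA. Of 2942 alternates 811 had RNA-seq reads (27.6%, 25.98 to 29.2), and of 7410 unannotated introns 2007 (27.1%, 26.1 to 28.1). The share grew with lariat reads, from 14.5% and 13.7% at 1 read to 57.4% and 84.8% at 100 or more. Of the 10 alternates with the highest rate, tup12 and atg5 had 142 and 116 RNA-seq reads, while vti1 and sfc9 had 0. The others of that group had 24 or more. From the fixed lists rpl35 and atp1 had 0 and rpl3002 had 4. All 10 alternates with the most lariat reads, psg2, yih1 and ufe1 among them, had 0. Across the 1268 host introns Spearman rho between alternate rate and annotated lariat reads was -0.0929. The mean rate was 4.26% in the lowest quintile of reads and 0.457% in the highest, while the share of introns with any alternate read ran the other way, from 51.6% to 75.6%. The rate has these reads as its denominator, so the measures are coupled.

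**Figure D2:**
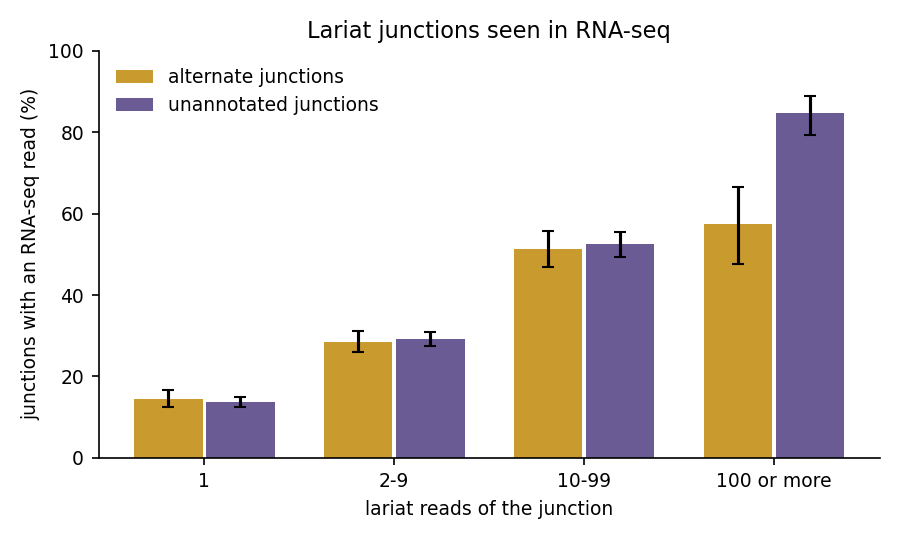
Share of lariat introns seen as RNA-seq junctions, by lariat reads. At 100 or more reads it was 57.4% for alternates and 84.8% for unannotated introns.

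Loss of upf1 raised alternate junctions in rps3, upf3 and aha1, among others. A downstream 5' site in rps3, a gene of the small ribosomal subunit (chromosome II, 4239039 to 4239123), had 0 and 0 reads in ED668 and 13 and 14 without upf1, at least 8.56-fold. An upstream 5' site in upf3, itself a decay factor (chromosome I, 2298971 to 2299192), went from 0 and 0 reads to 14 and 12, at least 8.24-fold. A downstream 5' site of the Hsp90 co-chaperone gene aha1 (chromosome II, 2149465 to 2149531) rose from 1 read in total to 46 (43.7-fold, 7.47 to 1765). Also raised were the mevalonate kinase gene erg12 (22.8-fold, 3.72 to 938) and the 14-3-3 gene rad25 (10.9-fold, 2.70 to 95.7). The proton pump genes vma7 (log2 2.28 ± 0.45 SE, adjusted p 0.0184) and vma8 (1.99 ± 0.58, 0.0452) followed, then SPBC685.08 (1.58 ± 0.44, 0.0424), btb3 (1.57 ± 0.40, 0.0321) and pet801 (1.54 ± 0.40, 0.0321). For vma7 this was 0.0786 ± 0.0219 against 0.543 ± 0.0703 RPM, reads scaled to library size (mean ± SD, n = 2).

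Alternate junctions that fell lay in SPBC1711.15c (-3.12 ± 0.47, adjusted p 0.0126), in the ribosome biogenesis gene alb1 (-2.07 ± 0.27, 0.0119), in SPAC17C9.11c (-1.35 ± 0.27, 0.0187) and in emc5 of the endoplasmic reticulum (-1.28 ± 0.32, 0.0321). SPBP4H10.12 fell by the test (-0.55 ± 0.10, 0.0145) but its RPM hardly differed (ratio 0.931, 0.820 to 1.06). Of 62 junctions tested 13 were up and 6 down with edgeR, against 3 and 2 with DESeq2 and 21 and 3 with aligned reads as scaling. With replicate block 0 passed, and 15 had unadjusted p below 0.05. The median log2 was 0.16, and 0.60 with aligned reads, so log2 values are relative to that shift. Leaving out the first ED668 library gave 7 calls, and leaving out the first or the second deletion library gave 0 each. On the ribosomal protein list 2 of 4 alternates rose, rps3 and rps1701 (1.05 ± 0.27), and 2 adjusted over the list alone. There rpl2502 (-0.44) and rpp40 (0.35, listed by name alone) did not pass. The fixed lists also gave upf3 as 1 of 1 for RNA decay, aha1 as 1 of 1 for heat shock, and 0 of 3 for splicing (lsm2 0.67, srp2 -0.26, prp10 0.21; 0 adjusted over the list alone). Junctions with an earlier predicted stop were up in 11 and down in 3 of 45 cases, and those with the annotated stop up in 0 and down in 2 of 9.

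Among unannotated junctions, loss of upf1 raised spliced transcripts on the strand opposite protein genes. SPNCRNA.997 opposite ypp1 (chromosome I, 4544962 to 4545040) had 0 and 0 reads against 44 and 29, at least 23.1-fold. A transcript antisense to the TOR regulator gene tsc2 had 0 and 0 against 46 and 22, at least 21.6-fold, and SPNCRNA.1427 opposite the cell wall sensor gene wsc1 was at least 20.3-fold higher. Next were the strand antisense to pet127 (at least 13.3-fold), SPNCRNA.1206 opposite the nuclear pore gene nup211 (at least 11.7-fold), SPNCRNA.1087 opposite gto1 (at least 11.4-fold) and the 5' region of the nitric oxide dioxygenase gene yhb1 (at least 8.56-fold). The transcript antisense to mrp7, a gene of the mitochondrial ribosome, rose from 1 read to 113 (107-fold, 18.9 to 4281), SPNCRNA.1202 opposite the sulfite reductase gene met10 42.8-fold (7.30 to 1727) and the 3' region of prp3 22.8-fold (5.98 to 194).

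**Figure D3:**
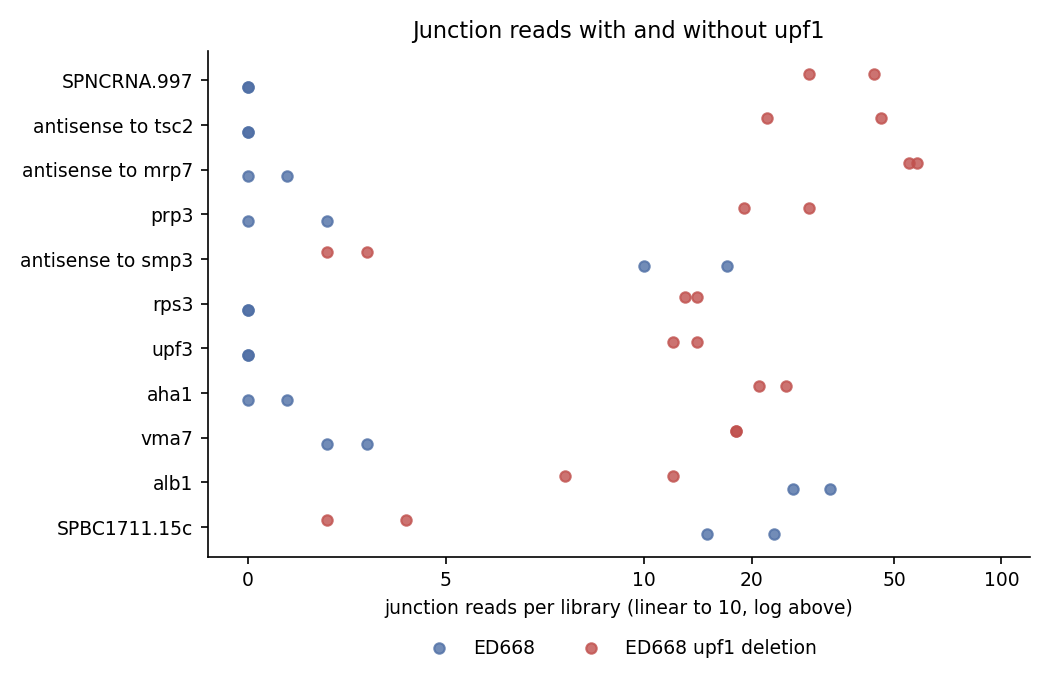
Junction reads per library in ED668 and in its upf1 deletion. The upf3 junction went from 0 and 0 reads to 14 and 12, and the alb1 junction from 26 and 33 reads to 12 and 8.

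Junctions lowered without upf1 were spread over location types. The 3' region of sgp1 went from 18 and 15 reads to 3 and 0 (ratio 0.0864, 0.0170 to 0.276). Falls were also found antisense to the mannosyltransferase gene smp3 (-2.70 ± 0.62, adjusted p 0.0031), opposite SPNCRNA.1673 (-2.66 ± 0.29, 1.15e-05), in the 3' region of the mitochondrial carrier gene oac1 (-2.21 ± 0.58), beside tam5 (-2.19 ± 0.29), in SPNCRNA.947 opposite dph4 (-2.13) and in SPNCRNA.1626 (-2.10). The last of the 10 were antisense to prl45 (-2.02), antisense to abc1 (-1.69) and in SPNCRNA.1236 (-1.66 ± 0.16, 5.81e-06). Of 186 junctions 47 were up and 39 down with edgeR, 24 and 17 with DESeq2, and 56 and 22 or 32 and 7 with aligned reads in either assignment to the deletion columns, with medians of 0.07, 0.31 and 0.34. Antisense to transcripts 22 of 54 were up and 6 down, in 3' regions 10 and 10 of 37, in noncoding RNAs 3 and 8 of 23, in exons 6 and 3 of 25, in 5' regions 3 and 2 of 18, between genes 2 and 6 of 15, and antisense to noncoding RNAs 0 and 2 of 8. On the lists, prp3 and sap49 of the U2 snRNP (1.47 ± 0.37, adjusted p 0.00579) were up as 2 of 2 splicing junctions, and the fibrillarin gene fib1 was down (-1.28 ± 0.19, 0.00014) with rrp8 (1.28) and bms1 (0.24) not passing. The exosome cofactor gene ski3 (1.42 ± 0.58, adjusted p 0.0605) passed only when adjusted over the list alone, and qcr6 of respiration (0.26) did not. The core stress, glycolysis and meiosis lists had no junction tested.

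Heat shock raised a junction of aha1, an exon junction of sap49 and junctions antisense to thp1, dbl4, mrp7 and trp1322. Junction reads of all RNA-seq tests here were scaled by library and not set against annotated junctions or gene levels. A rise of the whole transcript can therefore not be told from a change of splice site. In the RNA-seq of wild type and the dbr1 deletion, the downstream 5' site of aha1 rose from 1 read to 178 (155.8-fold, 27.6 to 6189), or 0.0320 ± 0.0453 to 5.51 ± 1.37 RPM (mean ± SD, n = 2). These are 1 library of each strain, so the SD also holds any difference between the strains. SPNCRNA.1282 opposite thp1, a DNA repair gene, rose from 1 read to 168 (147-fold, 26.04 to 5843), the strand antisense to dbl4 from 1 to 85 (74.4-fold, 13 to 2973) and an intron within an exon of sap49 (chromosome I, 2989591 to 2989642) from 3 to 114 (33.3-fold, 11.1 to 164). From 0 reads came the 3' region of SPAPB24D3.07c (at least 11.96-fold), the strand antisense to mrp7 (at least 11.4-fold) and SPAC8E11.08c (at least 10.8-fold). An osh2 exon rose 17.5-fold (4.54 to 150), the strand antisense to trp1322 by 3.08 ± 0.93 log2 units (adjusted p 0.0198) and an mfs1 exon by 2.85 ± 0.69 (0.0031). The single fall was in the 3' region of sce3 (-1.23 ± 0.41, 0.0382).

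Of 97 junctions 13 were up and 1 down in heat shock with edgeR, against 12 and 0 with DESeq2, and all 14 went in the called direction within each strain. Leaving out 1 library gave 4 calls without wild type in rich media, 4 without the dbr1 deletion in rich media, 4 without wild type in heat shock and 8 without the dbr1 deletion in heat shock. Of 3 splicing junctions 1 passed, sap49, and 3 adjusted over the list alone, with lsm4 (1 and 24 reads, ratio 21.01, 3.43 to 864) and prp10 (1.52 ± 0.59) joining it. The heat shock list gave aha1 as 1 of 1, and rpl2502 (-0.80) and qcr6 did not pass for ribosomal proteins and respiration.

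**Figure D4:**
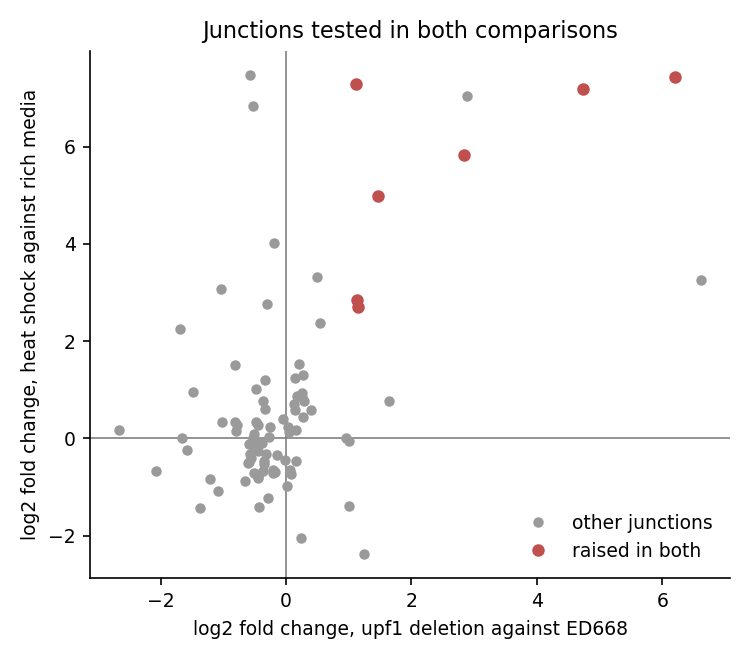
Log2 change in heat shock against log2 change without upf1, 1 point per junction. Across 91 junctions Spearman rho was 0.327.

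Diauxic shift raised a junction in the 5' region of prz1, the transcription factor of the calcineurin pathway. It went from 0 and 0 reads to 33 and 14 (at least 14.1-fold). The 3' region of SPAPB24D3.07c (at least 6.59-fold) and the mfs1 exon (2.59 ± 0.69, adjusted p 0.024) rose with it, and the junction opposite SPNCRNA.1694 fell (-2.97 ± 0.72, 0.024). These were 3 up and 1 down of 97 with edgeR and 0 with DESeq2, which had 9 at unadjusted p below 0.05. No call was left without wild type in rich media, the dbr1 deletion in rich media, wild type in diauxic shift or the dbr1 deletion in diauxic shift (0 each), and 1 was left without wild type in heat shock. The median log2 was 0.40, and 0.60 with aligned reads, so values are relative to that shift. On the lists rpl2502 (-0.88 ± 0.40, p 0.0379) passed only when adjusted over the list alone, and aha1, qcr6 and 3 splicing junctions gave 0.

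No junction passed the test for loss of dbr1, which does not show that they are unchanged. Of 97 junctions 0 passed with edgeR, where 3 had unadjusted p below 0.05, while DESeq2 called 2 up and 0 down and leaving out the dbr1 deletion in rich media gave 3. The nearest was the 3' region of SPAC343.20 (1.61, adjusted p 0.0919). The aha1 junction (1.16 ± 0.57, p 0.0498) passed only when adjusted over the list alone. With aligned reads as scaling the median log2 was -0.41.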

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

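Of the tests in this part, the shortest-distance rule for 3' sites and the base before the branch point were chosen only after the result was seen.

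For 80 forward-strand branches the condition columns held fewer reads than the total, and 419089 reads (11.1% of all branch reads) were missing there. The largest gaps were at rps2402 (122558 reads), put2 (73075), met14 (33131), twf1 (32736) and the RNA polymerase II gene rpb1 (28229), so 45 annotated introns have no condition ratio in the text. An A stood before the branch point in 97.5% of these branches against 66.1% of other forward branches (Fisher's exact p 5.21e-12). Another 1371 branches with 39954 reads (1.05%) were in no class list, and 556 of them had 1 read.

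Alternate 3' sites with many lariat reads were often missing from RNA-seq. Of 77 such junctions with at least 100 lariat reads and a host intron 45.5% (34.8 to 56.5) were seen, against all of 20 alternate 5' junctions (83.9 to 100%). Without the need for a host intron, 17 of 18 upstream and 5 of 5 downstream 5' junctions were seen. Low RNA-seq depth does not account for this, since the 5' junctions came from the same libraries. All listed 3' sites (100%) were the first AG past a shortest distance from the branch point, 8 bases on the forward and 7 on the reverse strand, while 84.6% of alternate 3' sites were the first AG more than 3 bases away. Where a branch point lies nearer than that to the annotated 3' site this rule would list a later site, which could be so for 196 downstream 3' alternates with 43907 reads (88.6% of that class), 6 of the 10 alternates with the most reads among them. These 196 also had 1826 RNA-seq junction reads, so some listed sites are joined. Listed upstream 3' sites follow the same rule. Of 41 upstream 3' junctions with at least 100 lariat reads, host intron or not, 17 were seen in RNA-seq. Whether psg2, yih1, ufe1 and vti1 use their listed or their annotated 3' site stays open.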

How the results depend on the processing

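Counts of called junctions depended on the tool and on single libraries. No named junction that had a value turned its direction. The naming rule took only junctions that moved alike in every replicate or strain, so a turn was hardly possible and its absence is no sign of robustness. Without the first or second deletion library 11 and 12 of 15 named upf1 alternates had a value, and 19 of 20 unannotated ones. For upf1 alternates DESeq2 called 5 junctions, adjusted p below 0.01 gave 0, and leaving out 1 library gave 0 to 17. With replicate block, pairing libraries of the same number, the count was 0, and paired deviations were uncorrelated (r 0.00323). For unannotated junctions, whose deletion columns carry no number, the replicate block gave 72 and 67 calls under either pairing. There DESeq2 called 41, adjusted p below 0.01 gave 57 and the second assignment of aligned totals 39. For dbr1 DESeq2 called 2 and leaving out 1 library gave 0 to 3. For heat shock the count was 9 without the filter, 8 at adjusted p below 0.01 and 4 to 20 with 1 library left out. For diauxic shift it was 0 with DESeq2, 0 without the filter, 0 at adjusted p below 0.01 and 0 to 3 with 1 library left out. The cause was not tested for any of these.

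Lariat introns more than 2-fold higher in heat shock numbered 461 with read totals, 543 without a read minimum and 177 against length peers, and lower introns 301, 1175 and 206. In diauxic shift higher introns numbered 476 with DESeq2 factors, 474 with TMM, 748 with read totals and 343 without a minimum, and lower ones 297 with read totals, 1726 without a minimum and 227 against length peers. At a minimum of 100 reads 8 introns named for heat shock stayed named.

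The alternate rate was 1.13% with hosts of at least 20 reads, 0.540% with 500, 0.607% with events of at least 5 reads, 0.566% with 10, 0.743% without ribosomal protein genes, 0.446% without branch points nearer to the annotated 3' site than any listed, and 0.0786% as the median intron. Exon skips over the length-expected ratio stood at 1.25 in heat shock and 1.02 in diauxic shift. With at least 2, 5 and 10 RNA-seq reads, 19.8%, 11.5% and 7.07% of alternates and 19.2%, 11.6% and 7.65% of unannotated introns were seen. Spearman rho of rate and reads was -0.0319 with hosts of 20 reads and -0.256 with reads thinned to 100. With at least 10 reads GTAAGT and CTRAY were found in 32.3% and 69.9% of annotated and 22.7% and 49.9% of unannotated introns.

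Not run were pseudocounts of 0.1 and 5 and the mean filter, which apply to normalized values, and for lariats the DESeq2 and edgeR tests, leave-one-out, adjusted p below 0.01, the replicate block, long or short gel alone and matching both ends within 3 bases, since their columns are sums.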

Other observations

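Of the tests in this part, the ratio without the 10 largest skips and the tests of earlier stops, of antisense junctions and of heat shock against upf1 were chosen only after the result was seen.

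The PSI fractions, whose denominator is not given, were above 0 for a small part of the unannotated junctions. Of 7412 junctions 356 had a PSI above 0 in wild type in rich media, 544 in heat shock and 634 in diauxic shift, with medians of 0.157, 0.0952 and 0.0602 among those seen. The dbr1 deletion gave 333, 514 and 545, and the ED668 libraries 736 and 754. Aligned reads in the same order were 12433793, 15188115 and 18855775 in wild type, 15601054, 16836042 and 12330328 in the dbr1 deletion, and 31706210 and 31884907 in ED668. Counts and medians are not corrected for depth and rest on single libraries, so they do not compare the conditions. At least 0.5 was reached by 82 junctions in wild type in rich media, 103 in heat shock and 64 in diauxic shift. The authors marked 15.3% of alternates, 15.2% of exon skips and 17.1% of unannotated introns as found in an earlier study. Their own conservation estimates gave an excess over background of 0.0975, 0.123 and -0.0352 for upstream 5' sites in the 3 other yeasts listed, 0.0894, 0.0744 and -0.0046 for downstream 5' sites, and -0.0498, -0.0273 and -0.1495 for downstream branch points.

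The upf1 deletion also raised transcripts opposite a kinesin gene and an autophagy gene region that the naming rule did not reach, chosen here after the values were seen. SPNCRNA.561 opposite the mitotic kinesin gene pkl1 rose by 2.44 log2 units (adjusted p 8.1e-05), and the 5' region of atg5 by 1.81 (0.0134). From few reads, the strand antisense to the glucan synthase gene mok12 rose 8.24-fold (2.53 to 42.5) and SPNCRNA.960 opposite gid5 11.9-fold (2.96 to 103.5). In the 3' region of SPAC343.20 a pair of junctions rose, 3.74-fold (3.06 to 4.605) and 14.3-fold (4.58 to 71.8). The sce3 3' junction, which fell in heat shock, stood at 42.1 ± 5.99 and 41.6 ± 6.03 RPM in ED668 and the upf1 deletion (mean ± SD, n = 2). Both deletion columns were scaled by the mean of their aligned totals, so the deletion SD also holds their difference in depth.

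Exon skip reads per annotated read were 3.02-fold higher in heat shock than in rich media. A few skips with many reads do not account for this, since the ratio was 3.04 without the 10 largest. Better recovery of long lariats in heat shock could account for most of it, as the observed skips were 1.25 times (1.2455, interval 1.00 to 1.51) those expected from length. Whether heat itself adds skipping stays open.

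Junctions sensitive to upf1 may mark spliced RNA that nonsense-mediated decay removes. In favour of this hypothesis, alternates with an earlier stop had a higher median log2 change than those with the annotated stop (0.27 and -0.51, difference 0.776, 45 and 9 junctions, permutation p 0.0464, BH 0.0464). Antisense junctions lay above other unannotated junctions (0.50 and -0.08, difference 0.587, 62 and 124 junctions, permutation p 0.00189, BH 0.00378). Junctions are not independent replicates, and a change in transcription in the upf1 deletion could give the same result, which these tables cannot exclude without gene-level values.

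Heat shock and loss of upf1 raised some of the same junctions. Across 91 junctions, which are not independent replicates, the log2 changes were correlated (Spearman rho 0.327, permutation p 0.00177, BH 0.00266, Pearson 0.540, permutation p 1e-05). Raised in both were 7 junctions, against 1.98 for independent lists, and 2 raised in heat shock were lowered without upf1. These 91 junctions had passed the filter on low counts in both comparisons. One with few reads in both controls could pass only if it was high without upf1 and in heat shock or diauxic shift. That selection favours shared rises, so the 1.98 and the permutation p values of this paragraph cannot show an excess over chance. The 7 were aha1, the strands antisense to mrp7 and dbl4, exons of mfs1 and sap49, SPAC8E11.08c and an intergenic junction on chromosome I. Heat shock and upf1 share no library, and diauxic shift, which shares its rich media libraries with heat shock and so is not separate evidence, was correlated as well (rho 0.354, permutation p 0.00067, BH 0.00201, Pearson 0.378, permutation p 0.00081), while the dbr1 change was not (rho 0.123, permutation p 0.244, Pearson 0.0505, permutation p 0.628).

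For the dbr1 comparison all 10 splits of the 6 libraries, the real one included, gave 0 junctions. With 0 at the real split no split could give fewer, so this cannot show whether its groups differ.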
